A study of Mus musculus with 2 samples.

How the data were processed

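The series holds 2 mouse libraries of CD11c-selected tumour cells, prepared with the 10x Genomics 3' chemistry version 2, which counts molecules at the 3' end of transcripts by UMI. Reads were processed by the authors with Cell Ranger 2.2.0 on genome build mm10, per the submitters' processing notes. The aligner settings and the annotation release are not given in the sources used here. The authors deposited raw UMI counts per gene and barcode for all 737280 barcodes of each library, with 27998 genes and no filter on cells. The 121 genes whose symbol is shared with another gene were kept apart by their identifiers. Gene positions came from the GENCODE M21 annotation of GRCm38, the assembly of mm10, in which 89 of the 89 genes chosen by the rule given below were found by identifier.

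Cells were called with the rule of that Cell Ranger version: the 99th percentile of UMIs among the 3000 barcodes with most UMIs was divided by 10. This gave thresholds of 2112 and 1905 UMIs in replicate 1 and replicate 2. Of 2013 and 1318 barcodes past it, 0 and 1 had under 200 genes and 83 and 89 had over 10% mitochondrial UMIs. The 30 and 12 cells with the highest Scrublet scores were then removed as doublets, which is 0.8% per 1000 cells called. The 1900 and 1216 cells left held 73% and 71.8% of all UMIs. At this depth a share of 0 in replicate 1 has an exact upper limit of 0.194% and in replicate 2 of 0.303%.

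Counts were scaled to 10000 per cell and log-transformed, and 2000 highly variable genes, 30 principal components, 20 neighbours and Leiden clustering at resolution 1.0 gave the clusters, with both libraries together and no integration (scanpy 1.11.5, leidenalg 0.10.2, scikit-learn 1.9.0, numpy 2.4.6, scipy 1.17.1, Python 3.11.15). The genes were split in 2 parts before clustering: 13904, including every cell type marker, could build clusters, and 14094, including every member of the fixed gene lists and Itgax, were held out. Only held-out genes were tested between classes, so that no gene that built a cluster is tested as a difference between clusters. Levels of some markers, which could build clusters, are given below without a test. Held-out genes still correlate with the others, so the tests describe classes defined in the same cells. A cluster was called by a class name with the suffix "like" if at least 3 fixed markers were raised in it, each at a log2 fold of at least 1 and in at least 20% of its cells, and if its top 10 genes did not hold more markers of another class. A cluster with very low UMI counts also needed a marker of its class among those 10. The 171 markers written for 20 classes matched 163 gene entries of the files. Names were thus rebuilt from markers and not taken from an annotation of the authors.

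UMI counts were summed per library and class for the 8 classes with at least 20 cells in each library. The sums were compared with edgeR 4.0.16 in R 4.3.3: filterByExpr, TMM scaling, a quasi-likelihood fit with the library as a block because the classes of a library come from the same capture, and Benjamini-Hochberg adjustment over 4681 held-out genes of 9098 genes past the filter. The fit had 16 sums, 7 residual degrees of freedom and a common biological coefficient of variation of 0.131. A gene was called at an adjusted p under 0.05. CPM values are scaled by TMM unless stated otherwise, and means and SDs are over the 2 libraries. The 16 fixed lists held 322 written genes. These matched 316 gene entries of the files, where a shared symbol such as Itgam counts each of its entries. Values of Itgam are those of a single entry. The lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, and again with the correlation estimated. With the estimate, in the 4 comparisons of classes only the lysosomal list of macrophage-like against cDC2-like cells passed. The genes named in the text followed a rule: per comparison, up to 2 genes with the largest absolute fold from each list among those called with the same sign in both libraries, the 4 largest rises and 4 largest falls among genes of at least 50 CPM in the higher class of both libraries, and Itgax, Flt3, Cd274 and Vcam1 in any case, up to 30 genes. Some genes that met this rule are not reported here. Ribosomal protein, mitochondrial, immunoglobulin and Gm- or Rik-named genes were left out of the largest rises and falls. Where a class had 0 counts of a gene over both libraries, the fold is a bound against a floor of 3 counts, and where it had 1 to 3, the pooled ratio is given with its counting interval. The bound takes the counts of the other class as exact, so it overstates the lower limit where those counts are few.

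Itgax was compared per cell after thinning each cell to 1900 UMIs, below the lowest threshold, so that no cell was left out. Free RNA was profiled in barcodes of at most 50 UMIs, and its share in the class sums was estimated from epithelial and erythroid markers at 0.757% to 3.09%. Epithelial-like cells, for which this estimate does not work, were given the mean of the other classes of their library. The tests were first run on counts simulated from these sums, with 5 draws for each comparison and 200 genes changed per draw. For macrophage-like against cDC2-like cells, 50.1% of genes changed 2-fold and 80.5% of those changed 4-fold were recovered, and 9.59% of calls were false. For resident macrophage-like against macrophage-like cells the values were 48%, 78.5% and 9.68%, for cDC1-like against cDC2-like cells 31%, 64.8% and 7.55%, and for mature DC-like against cDC2-like cells 17.5%, 47.6% and 11.1%. The false share was above the nominal 5% in each, so calls close to the threshold include more false ones than the adjusted p states. Camera called 0, 1, 0 and 0 lists in the same simulations. Those genes were simulated without correlation within lists, so these counts do not test the preset correlation that camera used.

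Classes, lists, tests, markers and most alternatives were fixed before the data were examined. Alternatives covered the cell threshold, mitochondrial limit, doublets, resolution, genes used for clustering (both parts of the split, without the members of the fixed lists), scaling by DESeq2 size factors, the DESeq2 1.42.0 Wald test, low-count filter, library block, free RNA subtraction, equal cells per class, and leaving out each library. Leaving out macrophage-like cluster 2 and, separately, macrophage-like cluster 8 was added after seeing the data. A planned comparison of macrophage-like with classical monocyte-like cells was not run because no cluster met the classical monocyte name.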

Results

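Single-cell RNA sequencing was carried out on CD11c-selected cells from the tumour microenvironment of PyMT mice on the C57BL/6N background. PyMT mice carry the polyoma virus middle T antigen and develop mammary tumours, and CD11c is the integrin encoded by Itgax that many dendritic cells and macrophages carry. The labels gave a single wild-type group of 2 libraries, called replicate 1 and replicate 2 here, with no other group to compare. Comparisons were therefore made between the cell classes found inside the selection, each measured in both libraries. Replicate 1 held 17369071 UMIs (unique molecular identifiers, counted once per captured molecule) and replicate 2 held 13317214. After filtering, 1900 cells of replicate 1 had a median of 5670 UMIs and 1600 genes, and 1216 cells of replicate 2 had a median of 7141.5 UMIs and 1768.5 genes. Nothing in the labels says that the libraries came from separate animals. A shift between the libraries shared by all classes was removed by the block. The p-values thus measure only the library-to-library spread left within classes, pooled over the 8 classes of the fit, which may be technical. Intervals and limits for counts of 0 cover counting error only.

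Macrophage-like cells, defined by C1qa, C1qb, C1qc, Adgre1, Apoe and related markers, were the most common class at 39.5% ± 3.19 of cells (SD, n = 2). This share depended on how clusters were named: it was 20.62% at resolution 0.5 and 22.92% when genes of both parts of the split built the clusters. Cluster 2, with 496 of these cells, met 3 of 10 markers. Next came cDC2-like cells (conventional dendritic cells type 2, with Cd209a and Clec10a among their markers) at 13.4% ± 4.89. Resident macrophage-like cells, with Folr2 and Cbr2 among their leading genes, made up 12.3% ± 7.92. Their cluster met 6 of 9 markers. Lyve1, a marker of this class, had 120 UMIs over all cells of replicate 1 and 8 over those of replicate 2. For Cd163, also a marker, these counts were 114 and 39. At most 8 of the 82 resident macrophage-like cells of replicate 2 thus had a Lyve1 UMI. The class of cDC1-like cells (Xcr1, Clec9a) made up 5.38% ± 0.509, cycling cells 5.08% ± 0.0326 and mature DC-like cells (Ccr7, Fscn1) 2.32% ± 0.37. The cycling class took its name from markers of division and not of a cell type. Its cluster 13, with 34 cells, also had 6 cDC1 markers raised, and these cells are not in the cDC1-like share. The resident macrophage-like share was 17.9% in replicate 1 (exact 95% interval 16.2 to 19.8, 341 of 1900 cells) and 6.74% in replicate 2 (5.4 to 8.3, 82 of 1216 cells), and these intervals did not overlap. The cDC2-like share was 9.95% (8.64 to 11.4) in replicate 1 and 16.9% (14.8 to 19.1) in replicate 2, again without overlap. Epithelial-like cells (5.08% ± 1.6) and fibroblast-like cells (1.55% ± 0.482) were also present in the selection. Neutrophil-like and B cell-like cells were found in replicate 2 at 1.32% (0.754 to 2.13) and 1.23% (0.692 to 2.03), against 0 of 1900 cells in replicate 1, for which the exact interval reaches 0.194%. No cluster met the markers of classical monocytes. The name was met by 5.76% of cells when barcodes of at least 1000 UMIs were kept and by 6.97% without doublet removal, and these sets shared 63 cells. Without doublet removal the cluster had 4 classical monocyte markers among its 10 leading genes, which included Cxcl9, Ly6c2 and Ms4a4c, and 198 of its 228 cells came from macrophage-like cluster 2. At 1000 or more UMIs it was led by Gpnmb, Spp1 and Arg1, with 130 of 215 cells from macrophage-like cluster 8 and 70 from cluster 2. Most cells that met this name in those settings were thus counted as macrophage-like in the values reported. Clusters that met no class held 14.1% ± 0.00698 of cells. Shares follow from a CD11c selection and from a UMI threshold, so they are shares of captured cells and not of the tumour.

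**Figure D1:**
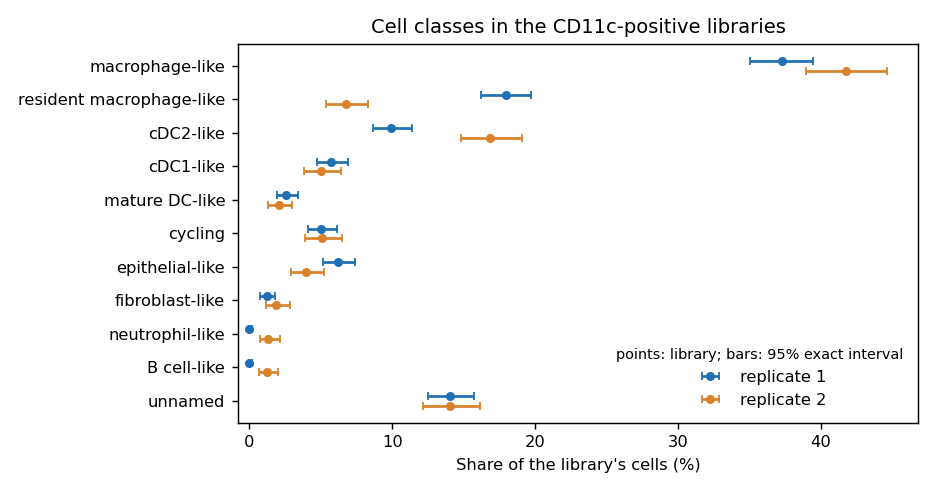
Share of cells (percent, x axis) in each named class. Points are the 2 libraries and bars are exact 95% binomial intervals, which cover counting error only. Macrophage-like cells lie at 37.3% and 41.8%, and resident macrophage-like cells at 17.9% and 6.74%.

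Itgax, the gene of the selection marker (chromosome 7, 128129547 to 128150657 in GRCm38/mm10), was highest, among the 8 classes in the fit, in macrophage-like cells at 166.5 ± 19.8 CPM (SD, n = 2) and in cDC2-like cells at 160.2 ± 29.4 CPM. It was lower in cycling cells (102.6 ± 14.9 CPM), cDC1-like cells (78.1 ± 21.7), mature DC-like cells (38.3 ± 7.17) and resident macrophage-like cells (22.8 ± 12.8). Fibroblast-like cells had 12.1 ± 1.56 CPM and epithelial-like cells 4.95 ± 5.11. The 16 neutrophil-like cells of replicate 2, which were outside the fit, had 225.2 CPM over 9 UMIs without TMM scaling, against 166.7 and 147.6 CPM in macrophage-like and cDC2-like cells of that library. In the edgeR fit the mean log2 level of 5 myeloid classes exceeded that of epithelial-like and fibroblast-like cells by 3.06 (SE 0.31). After each cell was thinned to 1900 UMIs, an Itgax UMI was present in 21.8% of cDC2-like, 21.4% of macrophage-like, 18.8% of cycling, 13.6% of cDC1-like and 6.1% of mature DC-like cells. The share was 2.4% in resident macrophage-like cells, against 1.3% in epithelial-like cells, which should lack the gene. The levels of these classes, 22.8 and 4.95 CPM, lay further apart, so the shares do not show that the resident macrophage-like signal is background. In replicate 2, however, resident macrophage-like cells had 13.8 CPM over 6 UMIs, near the 13.2 CPM over 4 UMIs of fibroblast-like cells. Whether the signal of that library is background is thus not settled. Median depths before thinning were 4258 and 5006 UMIs in resident macrophage-like cells and 8162 and 8360 in epithelial-like cells. Without thinning, the shares were 50.5% in cDC2-like, 49.2% in macrophage-like, 55.9% in cycling, 37.8% in cDC1-like, 15.1% in mature DC-like, 6.5% in resident macrophage-like and 5.7% in epithelial-like cells. Of the 23 fibroblast-like cells of each library, 2 had an Itgax UMI before thinning (8.7%) and 0 after it, for which the exact interval reaches 14.8%.

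**Figure D2:**
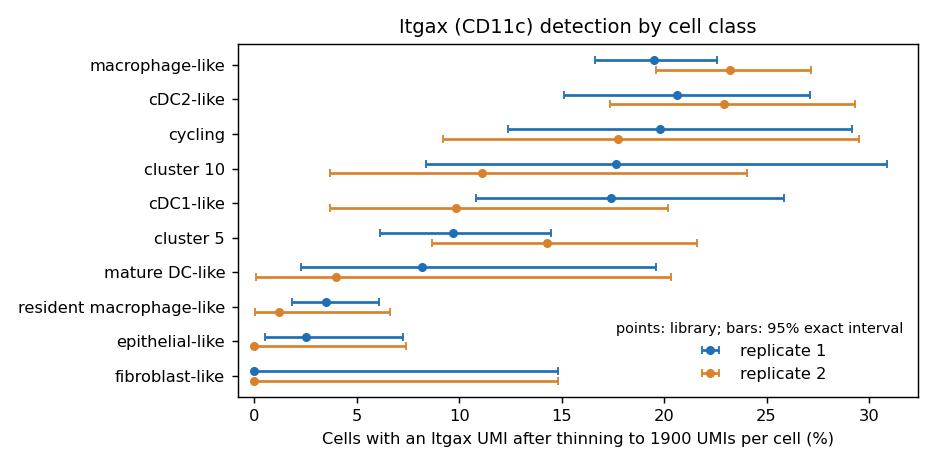
Percent of cells with at least 1 Itgax UMI (axis in percent) in each class after thinning every cell to 1900 UMIs. Points are the 2 libraries and bars are exact 95% binomial intervals. Macrophage-like and cDC2-like cells average 21.4% and 21.8%, resident macrophage-like cells 2.4%.

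Macrophage-like cells were compared with cDC2-like cells, the classes with the highest Itgax level among the 8 in the fit. Macrophage-like cells had 54.9-fold more Spp1, which encodes the secreted protein osteopontin (3901 ± 1138 against 72.4 ± 31.3 CPM, n = 2, log2 fold change 5.78, SE 0.34, adjusted p = 4.18e-13). Gpnmb, a lysosome-associated glycoprotein, was higher by 7.33 on the log2 scale (SE 0.81, 294.5 against 1.85 CPM), C3ar1, a complement receptor, by 5.22 (SE 0.31) and Olfml3 by 5.5 (SE 0.39). In cDC2-like cells Klrd1, which encodes CD94, was 63.3-fold higher (354.7 ± 9.31 against 5.48 ± 0.0342 CPM, log2 fold change −5.98, SE 0.27, adjusted p = 3.21e-15). Cd7 (−6.49, SE 0.35), P2ry10 (−4.80, SE 0.27) and Zbtb46 (−4.86, SE 0.52), a transcription factor of conventional dendritic cells, were also higher there. Flt3, the receptor of a growth factor that sustains dendritic cells, fell by 4.33 on the log2 scale in macrophage-like cells (SE 0.35, 3.2 against 68.3 CPM), while Vcam1 was higher there by 4.47 (SE 0.39). Itgax differed by 0.05 (SE 0.22, adjusted p = 0.916) and Cd274, the gene of PD-L1, by −0.31 (SE 0.28, adjusted p = 0.468), and neither passed. Of 4681 held-out genes tested, 599 rose and 553 fell in macrophage-like cells. Over all genes tested, the folds of the libraries had a Pearson correlation of 0.816 and a Spearman correlation of 0.699.

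Lysosomal genes rose together: 19 of 21 tested members rose and 0 fell (19 and 0 when adjusted over the list alone), among them Cd63 (4.36, SE 0.28) and the protease gene Ctsd (4.23, SE 0.26). The list passed limma's camera test with an adjusted p of 1.7e-21, and an adjusted p = 0.0456 with an estimated correlation. Scavenging and phagocytic receptors rose for 16 of 20 and fell for 1 (17 and 1 adjusted over the list alone; camera adjusted p = 1.07e-10, adjusted p = 0.0728 with an estimated correlation). In this list Stab1, a scavenger receptor with 3 counts in cDC2-like cells, had a pooled ratio of 74.5 (counting interval 25.4 to 361.8). Lipid handling genes rose for 13 of 18 and fell for 0 (14 and 1 adjusted over the list alone; 7.31e-08, and adjusted p = 0.0728 with an estimated correlation), with Spp1 and Gpnmb leading. Chemokines rose for 13 of 20 and fell for 2 (14 and 2 adjusted over the list alone; 1.85e-06, and adjusted p = 0.162 with an estimated correlation), including Ccl12 (5.15, SE 0.37) and Cxcl14, whose pooled ratio over 1 count was 52.5 (9.3 to 2086). Matrix remodelling genes rose for 11 of 20 and fell for 1 (12 and 1 adjusted over the list alone; 7.22e-05, and adjusted p = 0.168 with an estimated correlation), among them the collagenase gene Mmp13 with a pooled ratio of 37.8 over 3 counts (12.8 to 184.3) and Mmp2 with 11.1 (3.69 to 54.5). Of 14 pattern recognition receptors, 7 rose and 0 fell (7 and 1 adjusted over the list alone; 0.00199, and adjusted p = 0.18 with an estimated correlation), including Tlr12 (3.21, SE 0.58) and Tlr13 (2.9, SE 0.55).

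Of 20 cytokines and growth factors, 9 rose and 4 fell (10 and 4 adjusted over the list alone; camera adjusted p = 0.00708, and adjusted p = 0.0728 with an estimated correlation), with Igf1 (5.04, SE 0.47) and Tnfsf13b, the gene of BAFF (4.76, SE 0.43), among those that rose. Of 18 immediate early and heat shock genes, 5 rose and 0 fell (6 and 0 adjusted over the list alone; 0.017, and adjusted p = 0.222 with an estimated correlation). Of 23 interferon response genes, 7 rose and 1 fell (9 and 1 adjusted over the list alone; 0.0248, and adjusted p = 0.39 with an estimated correlation). Without the library as a block the immediate early list had an adjusted p of 0.123 and the interferon list of 0.124, so both calls were lost. The interferon call was also lost with fry (adjusted p = 0.13) and without macrophage-like cluster 8 (adjusted p = 0.0843). MHC class II presentation genes went the other way: 0 rose and 5 of 11 fell in macrophage-like cells (0 and 7 adjusted over the list alone; 1.27e-04, and adjusted p = 0.18 with an estimated correlation), with H2-DMb2 (−4.39, SE 0.28) and H2-Oa (−3.58, SE 0.23), which act in peptide loading. The other lists did not pass: 4 of 16 costimulation and checkpoint ligands rose and 6 fell, 8 of 22 myeloid transcription factors rose and 6 fell, 7 of 15 arginine, tryptophan and eicosanoid enzymes rose and 5 fell. Further, 3 of 22 glycolysis and hypoxia genes rose and 4 fell, 4 of 16 migration and growth factor receptors rose and 4 fell, and 1 of 15 MHC class I genes rose and 0 fell. Within these, Cd70 had 0 counts in macrophage-like cells and 6 in cDC2-like cells, and S1pr1 had 92 and 0. Against a floor of 3 counts over the 2 libraries, Cd70 was 6.63-fold lower and S1pr1 at least 9.26-fold higher in macrophage-like cells. Ptgs1 rose by 4.29 (SE 0.54), Maf had a pooled ratio of 74 over 1 count (13.2 to 2933), and Arg1, the gene of arginase, had a pooled ratio of 86.5 over 2 counts (23.8 to 715.8).

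Per-library log2 fold changes, computed with a prior count of 2, lay more than 1.5 times apart on the linear scale for 12 of the 28 named genes called in this comparison. In replicate 1 and replicate 2 they were 3.9 and 5.61 for Arg1, 2.79 and 4.44 for Ptgs1, 3.98 and 3.11 for Cxcl14. They were 3.86 and 4.7 for Igf1, 3.58 and 4.46 for Tnfsf13b, 3.92 and 4.73 for Cd63, 4.56 and 3.93 for Ctsd, and 3.12 and 5.31 for Vcam1. For the others they were 3.6 and 4.36 for Maf, 1.83 and 2.64 for Tlr13, 4.21 and 5.85 for Olfml3, and −4.20 and −4.93 for P2ry10. Much of the Spp1, Gpnmb and Arg1 level came from a single macrophage-like cluster of 138 cells. In a setting chosen after seeing the data, without that cluster Spp1 was higher than in cDC2-like cells by 3.29, Gpnmb by 4.63 and Arg1 by 1.07, the last with an adjusted p of 0.707. Klrd1 and Cd7 were uneven among cDC2-like cells. In the 143 of them that took the classical monocyte name at resolution 2.0, Klrd1 was at 428.7 and 514.6 CPM without TMM scaling in replicate 1 and replicate 2, against 201.8 and 199.5 CPM in the other cDC2-like cells. Cd7 was at 242.6 and 460.2 CPM there and at 34.4 and 59.6 CPM in the others, a split chosen after seeing the data. With 23 cells drawn per class and library, 187 genes rose and 109 fell.

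Resident macrophage-like cells were compared with macrophage-like cells. The class markers Cd209f and Cd209g had 782 and 423 UMIs over all cells of replicate 1. In replicate 2 they had 27 and 12, and Folr2 had 1383 and 360 in the 2 libraries. In replicate 2 the class held 82 cells, but 23 at 500 or more UMIs, 27 without doublet removal and 26 at resolution 2.0. Its replicate 2 sum may thus hold cells that those settings named otherwise. Without doublet removal 306 genes rose and 282 fell, 260 and 215 of them also called as reported. The chemokine Ccl8 was among the most abundant transcripts of resident macrophage-like cells at 12950 ± 2461 CPM against 433 ± 300.6 (n = 2, log2 fold change 5.07, SE 0.48, adjusted p = 1.29e-08). Ccl24 (5.17, SE 0.42), Fxyd2 (3.84, SE 0.28) and Pf4 (3.36, SE 0.29, 3276 against 315.8 CPM) were higher too, as were Gas6, a ligand of the receptors Axl and Mertk that act in uptake of dying cells (3.11, SE 0.2), the transcription factor genes Maf (2.95, SE 0.23) and Irf4 (2.87, SE 0.45), and Ccr2 (1.45, SE 0.19). Spp1 fell by 3.69 on the log2 scale (SE 0.3, 308.9 against 3901 CPM), Zmynd15 by 3.42 (SE 0.33), Il1r2 by 2.99 (SE 0.42) and Il1b by 2.05 (SE 0.34). Itgax fell by 2.65 (SE 0.29, adjusted p = 1.04e-07). Of 4681 held-out genes tested, 336 rose and 298 fell, and the library folds of all genes tested had a Pearson correlation of 0.621 and a Spearman correlation of 0.52. Without the library as a block these counts were 201 and 161.

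Of 22 glycolysis and hypoxia genes, 0 rose and 11 fell in resident macrophage-like cells (0 and 11 adjusted over the list alone; camera adjusted p = 5.02e-08, and adjusted p = 0.0639 with an estimated correlation), among them the lactate transporter gene Slc16a3 (−2.34, SE 0.42). Of 18 immediate early and heat shock genes, 8 rose and 0 fell (8 and 1 adjusted over the list alone; 4.28e-05, and adjusted p = 0.116 with an estimated correlation), with Jund (1.52, SE 0.22) and Hspa1b (1.52, SE 0.34). Chemokines rose for 10 of 20 and fell for 3 (10 and 4 adjusted over the list alone; 7.41e-04, and adjusted p = 0.316 with an estimated correlation). Lipid handling genes rose for 2 of 18 and fell for 8 (2 and 8 adjusted over the list alone; 0.00117, and adjusted p = 0.316 with an estimated correlation), Spp1 and Gpnmb (−3.57, SE 0.54) among the latter. Lysosomal genes rose for 1 of 21 and fell for 9 (2 and 11 adjusted over the list alone; 0.00125, and adjusted p = 0.344 with an estimated correlation). Here Ctsk, with 2 counts in resident macrophage-like cells, had a pooled ratio of 6.2 in favour of macrophage-like cells (1.62 to 52.7). Of 22 myeloid transcription factors, 8 rose and 3 fell (10 and 3 adjusted over the list alone; 0.0121, and adjusted p = 0.116 with an estimated correlation). Part of these list results came from macrophage-like cluster 8. Without it, a setting chosen after seeing the data, 0 glycolysis and hypoxia genes rose and 8 fell (adjusted p = 1.46e-04), and 7 immediate early and heat shock genes rose and 1 fell (adjusted p = 0.00277). Lysosomal genes then rose for 2 and fell for 5 (adjusted p = 0.0319), and lipid handling genes did not pass (adjusted p = 0.0726).

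MHC class II genes fell for 2 of 11 with 0 rising (0 and 5 adjusted over the list alone; camera adjusted p = 0.0096, and adjusted p = 0.389 with an estimated correlation), with H2-Oa at −2.78 (SE 0.51). MHC class I genes fell for 4 of 15 with 0 rising (0 and 4 adjusted over the list alone; 0.0297, and adjusted p = 0.389 with an estimated correlation), and with DESeq2 size factors this list had an adjusted p of 0.0541. The other 8 lists did not pass. In them 4 of 20 matrix remodelling genes rose and 7 fell, including Mmp12 (−2.54, SE 0.33) and Mmp13 (−2.18, SE 0.39). Of 20 scavenging receptors 6 rose and 2 fell, 4 of 20 cytokines rose and 4 fell, with Tnfsf13b at −2.89 (SE 0.36), and 3 of 16 costimulation and checkpoint ligands rose and 2 fell, with Havcr2, the gene of TIM-3, at −2.58 (SE 0.34). For 15 arginine, tryptophan and eicosanoid enzymes the counts were 3 and 2, with Alox5, an enzyme of leukotriene synthesis, at 3.33 (SE 0.48). For 14 pattern recognition receptors they were 2 and 1 with Tlr12 at −2.02 (SE 0.51), for 16 migration and growth factor receptors 1 and 3, and for 23 interferon response genes 2 and 0. Cd274 (−0.58, SE 0.33, adjusted p = 0.287) and Vcam1 (−0.48, SE 0.26, adjusted p = 0.256) did not pass, nor did Flt3, which had 0 counts in resident macrophage-like cells and was at least 2.25-fold lower (adjusted p = 0.0544).

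Per-library log2 fold changes lay more than 1.5 times apart for 16 of 27 named genes called. In replicate 1 and replicate 2 they were 4.32 and 5.28 for Ccl24, 4.5 and 5.66 for Ccl8, 3.84 and 3.19 for Fxyd2, 2.56 and 3.25 for Maf, 0.73 and 2.17 for Hspa1b. Among falling genes they were −3.33 and −4.34 for Spp1, −3.50 and −5.63 for Gpnmb, −2.66 and −4.74 for Zmynd15, −2.65 and −3.28 for Il1r2, −2.20 and −3.56 for Itgax. Further values were −2.26 and −2.87 for Havcr2, −2.36 and −3.04 for Mmp12, −2.55 and −1.65 for Slc16a3, −2.25 and −0.20 for Ctsk, −1.96 and −0.97 for Tlr12, and −2.73 and −1.94 for Arg1. Arg1 fell by 2.55 (SE 0.6), but without the macrophage-like cluster of 138 cells, a setting chosen after seeing the data, it was higher in resident macrophage-like cells by 2.62 (adjusted p = 0.0798). Spp1 then fell by 1.19 (adjusted p = 0.00682) and Gpnmb was at −0.80 (adjusted p = 0.425). Hspa1b was at −0.11 without doublet removal, DESeq2 called 186 falling genes, and with 23 cells per class and library 55 genes rose and 52 fell.

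The comparison of cDC1-like with cDC2-like cells set the conventional dendritic cell subsets side by side. Of the 394 cDC2-like cells, 143 took the classical monocyte name at resolution 2.0, and the comparison was not repeated without them. Irf8, a transcription factor that cDC1 cells require, was 9.19-fold higher in cDC1-like cells (905.2 ± 148.9 against 102.1 ± 34.9 CPM, n = 2, log2 fold change 3.2, SE 0.24, adjusted p = 2.44e-10). Ncoa7 (3.62, SE 0.32), the chemokine receptor gene Cxcr3 (3.5, SE 0.77) and the scavenger receptor gene Cd36 (3.45, SE 0.36) were also higher. Mcemp1 was lower by 33.9-fold (6.62 against 217.9 CPM, −5.08, SE 0.36), as were Pltp (−4.95, SE 0.46), Pxdc1 (−4.81, SE 0.57) and the lectin gene Clec4n (−4.78, SE 0.44). Cd7 had 1 count in cDC1-like cells, with a pooled ratio of 243.3 in favour of cDC2-like cells (43.5 to 9633). Irf4, a transcription factor of cDC2 cells, likewise had 1 count and a pooled ratio of 39 (6.77 to 1561). Itgax was at −1.03 (SE 0.26, adjusted p = 0.00682) and Cd274 at −1.47 (SE 0.43, adjusted p = 0.0214), while Flt3 (0.66, SE 0.28, adjusted p = 0.142) and Vcam1 (0.45, SE 0.74, adjusted p = 0.811) did not pass. Of 4681 held-out genes tested, 201 rose and 399 fell in cDC1-like cells, and the Pearson and Spearman correlations of the library folds over all genes tested were 0.587 and 0.477.

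Lysosomal genes fell for 12 of 21 and rose for 2 in cDC1-like cells (13 and 2 adjusted over the list alone; camera adjusted p = 1.73e-04, and adjusted p = 0.34 with an estimated correlation). Costimulation and checkpoint ligands fell for 7 of 16 and rose for 1 (7 and 1 adjusted over the list alone; 0.00497, and adjusted p = 0.154 with an estimated correlation), Cd274 and Sirpa (−3.00, SE 0.45), which encodes a receptor of CD47, among them. Scavenging and phagocytic receptors fell for 8 of 20 and rose for 1 (8 and 2 adjusted over the list alone; 0.00497, and adjusted p = 0.467 with an estimated correlation). Cd36 was the member that rose, and Itgam, the gene of CD11b, was at −3.45 (SE 0.45). Chemokines fell for 8 of 20 and rose for 0 (8 and 0 adjusted over the list alone; 0.00947, and adjusted p = 0.52 with an estimated correlation), with Ccl9 (−4.65, SE 0.38) and Ccl6 (−2.81, SE 0.29). The other 12 lists did not pass. Among them 5 of 15 MHC class I genes rose and 1 fell, 1 of 11 MHC class II genes rose and 3 fell, and 2 of 20 cytokines rose and 6 fell, with Osm at −3.15 (SE 0.48) and Il6, at 2 counts, with a pooled ratio of 27.6 in favour of cDC2-like cells (7.43 to 230.8). In the arginine, tryptophan and eicosanoid list 0 of 15 rose and 4 fell, and the cyclooxygenase gene Ptgs2 was at −4.57 (SE 0.45). Alox5 had 0 counts in cDC1-like cells and 15 in cDC2-like cells, 2.78-fold lower against the floor of 3 counts. For glycolysis and hypoxia genes the counts were 0 and 4 of 22, with Hilpda at −3.84 (SE 0.36). For lipid handling they were 2 and 4 of 18, with Fabp4 at 2 counts and a pooled ratio of 20.6 (5.51 to 173.3). For matrix remodelling they were 2 and 6 of 20, with Timp1 at −4.16 (SE 0.79) and Ecm1 at 1 count and a pooled ratio of 16.1 (2.68 to 659.5). Of 22 myeloid transcription factors 3 rose and 6 fell, with Zeb2 at −3.78 (SE 0.41). Of 14 pattern recognition receptors 1 rose and 5 fell. Tlr7 had 0 counts in cDC1-like cells and 11 in cDC2-like cells, 2.04-fold lower against that floor. Of 16 migration and growth factor receptors 1 rose and 5 fell. Interferon response genes rose for 1 of 23 and fell for 4, and immediate early and heat shock genes rose for 1 of 18 and fell for 2.

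For 22 of 28 named genes called, the folds of the libraries lay more than 1.5 times apart. For those reported here, the values in replicate 1 and replicate 2 were 2.64 and 3.68 for Irf8, 2.04 and 3.38 for Cxcr3, 2.73 and 3.99 for Cd36. Among falling genes they were −5.62 and −7.04 for Cd7, −4.32 and −3.10 for Irf4, −3.50 and −6.57 for Pxdc1, −3.27 and −5.47 for Clec4n, −1.66 and −5.92 for Sirpa, −2.22 and −4.71 for Itgam, −2.75 and −6.61 for Zeb2. They were −3.42 and −7.06 for Ccl9, −2.04 and −3.60 for Ccl6, −3.02 and −5.76 for Ptgs2, −2.93 and −4.11 for Il6, −2.20 and −3.74 for Osm. Further pairs were −3.06 and −4.94 for Hilpda, −4.53 and −0.43 for Fabp4, −2.82 and −4.19 for Timp1, −1.92 and −3.27 for Ecm1, −0.57 and −1.50 for Itgax, and −1.01 and −1.88 for Cd274. The calls of Itgax and Cd274 were lost in DESeq2 at −1.01 and −1.43 and with 23 cells per class and library at −0.64 and −1.88, a setting with 53 rising and 118 falling genes.

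Mature DC-like cells, with Fscn1 and Ccr7 among their leading genes, were compared with cDC2-like cells, whose 10 leading genes also held Ccr7. The 143 cDC2-like cells that took the classical monocyte name at resolution 2.0 were kept in this comparison too. Cd200, the gene of an inhibitory surface ligand, was 117.6-fold higher in mature DC-like cells (322.6 ± 32.5 against 2.62 ± 0.427 CPM, n = 2, log2 fold change 6.88, SE 0.39, adjusted p = 5.39e-13), and Serpinb6b was higher by 6.19 (SE 0.35, 836.9 against 11.1 CPM). The chemokine genes Ccl22 (5.21, SE 0.56, 3631 against 97.1 CPM) and Ccl5 (4.55, SE 0.37, 6984 against 297.4 CPM) were higher, and so were Fabp5 (4.93, SE 0.44), Cd63 (4.22, SE 0.29), Il12b, which encodes a subunit of interleukin-12 (3.94, SE 0.46), Il15 (3.39, SE 0.66) and Irf8 (3.24, SE 0.24). Cd274 rose by 2.17 (SE 0.33, 150.2 ± 50.8 against 31.5 ± 0.364 CPM, adjusted p = 2.62e-05), and Vcam1 by 2.49 (SE 0.73). Itgax fell by 2.04 (SE 0.4, adjusted p = 4.91e-04), and Flt3 was at 0.45 (SE 0.37, adjusted p = 0.507). Several genes of cDC2-like cells had 0 counts in mature DC-like cells: Cd7 was at least 25.4-fold lower and Itgam at least 9.82-fold lower. Tmem150c, with 0 counts in cDC2-like cells, was at least 40.1-fold higher, and M1ap, with 1 count there, had a pooled ratio of 166.3 (27.6 to 6794). Of 4681 held-out genes tested, 302 rose and 359 fell, against 341 and 210 by DESeq2. The library folds of all genes tested correlated at 0.526 (Pearson) and 0.453 (Spearman). The median log2 fold change of all genes tested was −0.20, against −0.11 with DESeq2 size factors in edgeR and −0.01 in DESeq2, and camera tests lists relative to the other genes.

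Costimulation and checkpoint ligands rose for 6 of 16 and fell for 2 in mature DC-like cells (7 and 2 adjusted over the list alone; camera adjusted p = 0.00237, and adjusted p = 0.09 with an estimated correlation), among them Cd200, Cd274 and Cd70 (4.83, SE 0.8). MHC class I genes rose for 8 of 15 and fell for 2 (10 and 2 adjusted over the list alone; 0.00237, and adjusted p = 0.462 with an estimated correlation). Interferon response genes rose for 6 of 23 and fell for 0 (7 and 0 adjusted over the list alone; 0.0276, and adjusted p = 0.526 with an estimated correlation), a call that was lost without the library as a block (adjusted p = 0.0585). Glycolysis and hypoxia genes rose for 0 of 22 and fell for 8 (0 and 8 adjusted over the list alone; 0.0276, and adjusted p = 0.462 with an estimated correlation). Pattern recognition receptors rose for 0 of 14 and fell for 4 (0 and 5 adjusted over the list alone; 0.0276, and adjusted p = 0.462 with an estimated correlation), with Clec4n at −3.49 (SE 0.53). The other 11 lists did not pass. In these, 1 of 11 MHC class II genes rose, H2-Eb2 (4.57, SE 0.45), and 6 fell, led by the peptide loading gene H2-DMb1 (−3.28, SE 0.26). Chemokines rose for 4 of 20 and fell for 1, cytokines rose for 2 of 20 and fell for 3, lysosomal genes rose for 3 of 21 and fell for 7, and scavenging receptors rose for 0 of 20 and fell for 6. Lipid handling genes rose for 1 of 18, Fabp5, and fell for 3, with Scd2 at 0 counts and at least 3.89-fold lower and Pltp at 3 counts and a pooled ratio of 20.8 in favour of cDC2-like cells (7.04 to 101.1). Of 15 arginine, tryptophan and eicosanoid enzymes 1 rose, Il4i1 (4.32, SE 0.32), and 3 fell, with Tbxas1 at 0 counts and at least 3.95-fold lower. Of 20 matrix remodelling genes 1 rose and 4 fell, with Thbs1 at 2 counts and a pooled ratio of 23.2 (6.36 to 192.5). Of 16 migration and growth factor receptors 4 rose and 6 fell, with Itgb7 at −3.78 (SE 0.56). S1pr1 had 4 counts in mature DC-like cells and 0 in cDC2-like cells, 7.65-fold higher against the floor of 3 counts. Of 22 myeloid transcription factors 4 rose and 2 fell, and of 18 immediate early and heat shock genes 0 rose and 4 fell. Outside the lists, Cd300a had 3 counts in mature DC-like cells and a pooled ratio of 25.1 in favour of cDC2-like cells (8.53 to 122.2), and Arhgap18 had 1 count and a pooled ratio of 21.1 (3.71 to 840).

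For 13 of 29 named genes called, the folds of the libraries lay more than 1.5 times apart. In replicate 1 and replicate 2 they were 4.89 and 3.97 for H2-Eb2, 1.82 and 2.49 for Cd274, 3.54 and 4.29 for Il12b, 1.7 and 2.81 for Vcam1, 4.6 and 5.7 for M1ap, 1.73 and 3.67 for S1pr1. Falling genes had −1.65 and −2.39 for Itgax, −2.21 and −4.42 for Clec4n, −4.92 and −5.77 for Itgam, −5.27 and −2.52 for Itgb7, −2.87 and −6.88 for Pltp, −2.34 and −6.65 for Thbs1, and −5.05 and −2.64 for Arhgap18. The class held 49 and 25 cells, and with 23 cells per class and library 162 genes rose and 166 fell. Cd70, Il12b and Tmem150c kept their direction in DESeq2 at 5.03, 4.18 and 8.47 without passing.

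**Figure D3:**
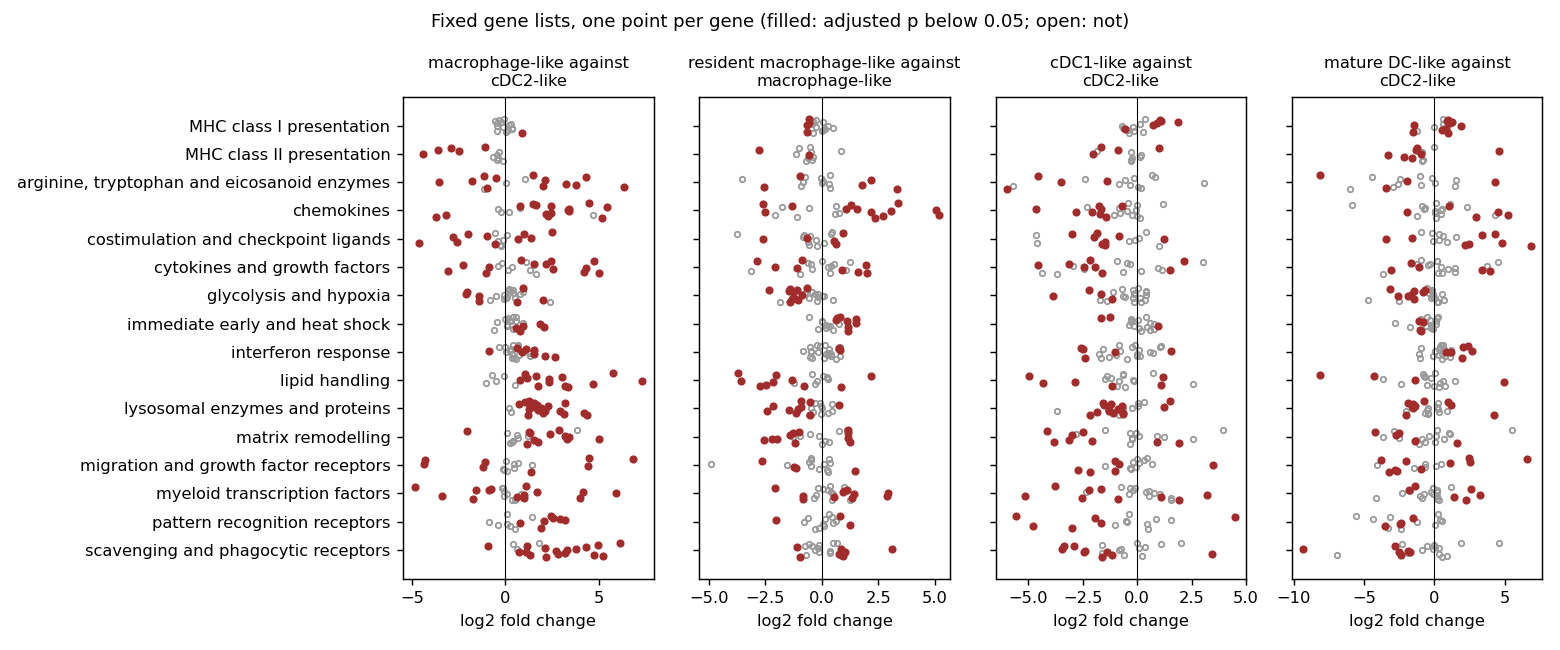
Log2 fold change (axis, log2 scale) of each tested member of the fixed gene lists in the 4 comparisons of cell classes. Each point is a gene, and filled points passed at an adjusted p under 0.05. Of 21 lysosomal genes, 19 rose in macrophage-like against cDC2-like cells, and 11 of 22 glycolysis and hypoxia genes fell in resident macrophage-like against macrophage-like cells.

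Several of the genes named above lie at the following positions of GRCm38/mm10 and are annotated as protein-coding. Spp1 spans 104435118 to 104441050 of chromosome 5, Gpnmb 49036546 to 49070929 of chromosome 6, Klrd1 129591782 to 129598775 of chromosome 6 and Cd7 121036747 to 121039418 of chromosome 11. Ccl8 spans 82115185 to 82116799 of chromosome 11, Ccl24 135569937 to 135573049 of chromosome 5, Irf8 120736358 to 120756694 of chromosome 8 and Cd36 17781690 to 17888801 of chromosome 5. Cd200 spans 45382135 to 45409053 of chromosome 16, Ccl22 94745590 to 94751699 of chromosome 8 and Serpinb6b 32965209 to 32979067 of chromosome 13. Cd274 spans 29367455 to 29388095 of chromosome 19, Flt3 147330741 to 147400489 of chromosome 5, Vcam1 116109949 to 116129688 of chromosome 3 and Arg1 24915221 to 24927484 of chromosome 10. Each library was sequenced from the 3' ends of transcripts, so the values count transcripts of the gene and not its exons.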

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

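All tests of explanations in this part were chosen after the result was seen. The labels hold a single group, so no biological explanation was tested for any pattern here.

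Cells and RNA outside the comparisons gave clear signals. Cluster 5, with 342 cells of both libraries and Retnla, Ear2, Lyz1 and Fn1 among its leading genes, and cluster 10, with 96 cells and Gzmc, Xcl1, Cd3g and Klre1, met no class name. In replicate 2, 16 neutrophil-like and 15 B cell-like cells were found that entered no comparison. In barcodes of at most 50 UMIs the milk protein gene Csn3 stood at 7129 CPM in replicate 1 and 4776 CPM in replicate 2, against 90.6 and 44.2 CPM in macrophage-like cells and 10700 and 11880 CPM in epithelial-like cells. These levels are without TMM scaling.

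The resident macrophage-like share differed between the libraries, at 17.9% and 6.74%. A UMI threshold that removed these cells from replicate 2 would bring the shares together at a lower threshold. The ratio of replicate 1 to replicate 2 was 3.24 at 1000 or more UMIs and 5.95 at 500 or more, against 2.66 in the values reported. Each threshold also built and named the clusters anew, and cells with this name in replicate 2 numbered 77 and 23, against 82. These ratios cannot separate the threshold from the naming, so they do not decide on this explanation. The size of the difference depended on the settings, with 5.68 without doublet removal and 5.34 at resolution 2.0. A shifted cluster boundary would leave the marker genes level over all cells, but all 9 markers with at least 100 UMIs were higher in replicate 1, with a median ratio of 2.88 and a range of 1.37 to 26.6. Yield in dissociation or selection, and differences between tumours or animals, stay open and were not tested.

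Epithelial-like and fibroblast-like cells were present inside the CD11c selection. Droplets that also held a CD11c-positive cell would carry abundant myeloid transcripts, but the highest median level of 7 abundant myeloid genes in these classes was 4.64% of that in macrophage-like cells. The bound was 20% for each gene, and the highest was Ptprc in fibroblast-like cells of replicate 1 at 12.9%. These levels are of class sums, so they argue against a myeloid cell in most of these droplets but cannot exclude it in a minority. In epithelial-like and fibroblast-like cells of replicate 1 the medians were 10.8% and 10.9% of the free RNA level. Free RNA there was estimated at 1.59% and 2.61%, the former from the other classes. In replicate 2 the medians were 1.72% and 3.51%, against estimates of 1.31% and 0.757%. Mixed droplets in a minority of these cells stay open, and so does carry-over of unbound cells in the selection, which was not tested.

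Neutrophil-like and B cell-like cells appeared in replicate 2. A UMI threshold that hid them in replicate 1 would release them at a lower threshold, but at 500 or more UMIs replicate 1 held 2 such cells and replicate 2 held 58. Neutrophils broken open in the suspension of replicate 1 would leave their RNA outside cells, but S100a8 plus S100a9 in barcodes of at most 50 UMIs were at 0.22 times the CPM of replicate 2. The genes differed, with S100a8 at 57 CPM in replicate 1 and 128.3 CPM in replicate 2 and S100a9 at 0.982 and 138.4 CPM, so some broken neutrophils in replicate 1 are not excluded. Differences in tissue, blood content or selection between the samples stay open and were not tested.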

How the results depend on the processing

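The settings without macrophage-like cluster 2 or cluster 8 were chosen after seeing the data, and all others before. Cells numbered 2420 and 1410 at 500 or more UMIs and 1675 and 1076 at 5% mitochondrial UMIs or less. Shares depended on how clusters took their names. The macrophage-like share of 39.5% moved to 35.12% at 500 or more UMIs, 32.94% at 1000 or more, 20.62% at resolution 0.5, 28.05% at resolution 2.0 and 22.92% with all but the list genes in the clustering. The unnamed share of 14.1% moved to 21.6%, 16.31%, 43.74%, 30.4% and 31.08% in the same order, and to 13.88% at 5% mitochondrial UMIs or less and 13.84% without doublet removal. The resident macrophage-like share of 12.3% was 0% at resolution 0.5, 5.67% at 500 or more UMIs, 7.34% without doublet removal and 6.78% at resolution 2.0. In replicate 2 it was 6.74% as reported and 1.63%, 2.2% and 2.14% in the last 3 settings. Classical monocyte-like cells, 0% as reported, were 6.76% at 500 or more UMIs, 5.76% at 1000 or more, 6.97% without doublet removal and 6.1% at resolution 2.0. The clusters with this name held partly shared cells. At 1000 or more UMIs and without doublet removal they shared 63 of 215 and 228 cells, the former led by Gpnmb, Spp1 and Arg1 and the latter with Cxcl9, Ly6c2 and Ms4a4c in the lead. At resolution 2.0 the name went to a cluster of 145 cells, 143 of them cDC2-like as reported, and to a cluster of 45 cells led by Cxcl9, Ms4a4c and Ly6c2 among others. Of those 45, 42 carried the name without doublet removal and 43 at 1000 or more UMIs. The cDC1-like share was 4.63% at 500 or more UMIs and 6.59% at resolution 0.5, the cDC2-like share 8.27% at resolution 2.0, the epithelial-like share 2.8% at 5% mitochondrial UMIs or less and the fibroblast-like share 2.14% at 500 or more UMIs. Cycling cells were 4.82% at 500 or more UMIs, 4.59% at 1000 or more, 5.23% at 5% mitochondrial UMIs or less, 5.14% without doublet removal, 3.88% at resolution 0.5, 4.82% at resolution 2.0 and 5.48% with all but the list genes. Without thinning, cells with an Itgax UMI were 49.2% of macrophage-like, 6.5% of resident macrophage-like, 37.8% of cDC1-like, 50.5% of cDC2-like, 15.1% of mature DC-like, 5.7% of epithelial-like, 8.7% of fibroblast-like, 55.9% of cycling, 26.7% of cluster 10 and 42.1% of cluster 5 cells, since deeper cells show more genes. With equal cells, 23 per class and library, fewer counts were left: 187 rose and 109 fell in macrophage-like against cDC2-like cells, 55 and 52 in resident macrophage-like against macrophage-like, 53 and 118 in cDC1-like against cDC2-like, and 162 and 166 in mature DC-like against cDC2-like cells. Without the library as a replicate block, 201 rose and 161 fell in resident macrophage-like cells. DESeq2 called 186 falling genes there and 210 in mature DC-like cells. Arg1 was higher in resident macrophage-like cells by 3.25 at 1000 or more UMIs, by 1.6 with equal cells and by 2.62 without cluster 8. The value without cluster 8 shows that its fall rested on that cluster. Hspa1b was at −0.11 without doublet removal, and the cause was not tested. With an estimated correlation 1, 0, 0 and 0 lists passed in the 4 comparisons, against 10, 8, 4 and 5. Without cluster 8, 9, 8, 4 and 5 passed, and without the replicate block 8, 8, 4 and 4. With fry 1 passed for resident macrophage-like cells, glycolysis and hypoxia, and 8 for mature DC-like cells. Those 8 did not include the interferon list (fry adjusted p = 0.318) and held lists that camera had not called. In cDC1-like cells fry lost the scavenging receptors (adjusted p = 0.0621) and the chemokines (adjusted p = 0.0982). Of 120 named gene results, 119 kept direction and call with DESeq2 size factors, 105 in DESeq2 with the other 15 losing the call, 118 with free RNA subtracted, 120 without cluster 2 and 115 without the replicate block. With equal cells 82 stayed the same, 18 lost the call, 1 reversed and the rest were not tested. Leaving out either library moved 50 of 120, where the remaining library's fold lay at least the SD of both library folds from the fitted fold. Library folds carried a prior count of 2 and did not come from the fit. The 50 therefore cannot separate this change of method from dependence on a library. Leaving out a library left no residual degrees of freedom, so it gave folds and shares and no counts of calls. The macrophage-like share then lay between 37.3% and 41.8% and the resident macrophage-like share between 6.74% and 17.9%. The comparison with classical monocyte-like cells and its alternatives were not run, and at resolution 0.5 the resident macrophage-like comparison had no class to test. Of the classes compared, mature DC-like cells were the fewest, with 49 and 25 cells.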

Other observations

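The clusters compared in this part were chosen after the data were seen, and tested on 4815 held-out genes. Among macrophage-like cells, cluster 8 (138 cells, with Gpnmb, Spp1 and Arg1 leading) was compared with cluster 1 (557 cells), and 242 genes rose and 280 fell. Gpnmb rose by 4.9 on the log2 scale (SE 0.48), Spp1 by 4.5 (SE 0.33) and Fabp5 by 3.98 (SE 0.38). Arg1 was at 164 and 1017 CPM in cluster 8 in replicate 1 and replicate 2, against 0 and 4.04 CPM in cluster 1. Of 22 glycolysis and hypoxia genes, 15 rose and 0 fell (camera adjusted p = 1.15e-14, and adjusted p = 0.00952 with an estimated correlation), including Hilpda (2.06, SE 0.28) and Bnip3 (2.02, SE 0.34). Of 18 immediate early and heat shock genes, 1 rose and 14 fell (1.02e-12, and adjusted p = 0.00952 with an estimated correlation), including Egr1 (−2.27, SE 0.36) and Hspa1a (−1.99, SE 0.43). Of 11 MHC class II genes, 0 rose and 8 fell (3.19e-09, and adjusted p = 0.0622 with an estimated correlation), including H2-Eb1 (−2.90, SE 0.45). Bnip3 differed between the libraries, at 1.17 and 2.59. Cluster 2 (496 cells, 177 genes rose and 98 fell against cluster 1) had less Itgax than cluster 1, by −1.30 (SE 0.21), and more Ccr2, by 2.6 (SE 0.2).

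Cluster 5, which held 11.4% of cells in replicate 1 and 10.4% in replicate 2, differed from macrophage-like cluster 1 and from cDC2-like cluster 4. Against cluster 1, 633 genes rose and 607 fell. Lyz1 rose by 6.23 (SE 0.47), Fn1 by 5.08 (SE 0.37), Ccl6 by 4.52 (SE 0.33) and Mmp19 by 4.38 (SE 0.37). Of 22 lysosomal genes, 0 rose and 17 fell (4.31e-12, and adjusted p = 0.245 with an estimated correlation), including Cd63 (−4.09, SE 0.26). Against cluster 4, 402 genes rose and 412 fell, and the lysosomal list went the other way: 7 of 22 rose and 2 fell (0.00132, and adjusted p = 0.397 with an estimated correlation). Hmox1 rose by 3.52 (SE 0.36), and Klrd1 was at −4.38 (SE 0.29). Ear2 stood at 1651 and 2034 CPM in cluster 5 in replicate 1 and replicate 2, and at 18.1 and 4.55 CPM in cluster 1. Of cluster 5 cells, 12% had an Itgax UMI after thinning.

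Cluster 10 carried lymphocyte genes inside the CD11c selection. All CPM values of this paragraph are without TMM scaling. Xcl1 stood at 3310 and 2500 CPM and Gzmc at 3127 and 2804 CPM in replicate 1 and replicate 2. Cd3g was at 336.3 and 505.4 CPM, Klre1 at 375.6 and 340.5 CPM and Ncr1 at 83 and 180.9 CPM. Cd3g and Ncr1 had 0 CPM in macrophage-like cells of replicate 1, and 0.535 and 0.268 CPM in those of replicate 2. Itgax in cluster 10 was at 117.9 and 85.1 CPM, and 14.4% of its cells had an Itgax UMI after thinning.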
